A study of Homo sapiens with 4 samples.

How the data were processed

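Messenger RNA was profiled on 1 array for each of 4 groups of SCP2 cells, a human breast cancer line. Per the labels, the groups were vector control cells and cells overexpressing DLC1, each without and with TGF-beta. The dose and the time of the TGF-beta treatment are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol from trypsinised cultures and reverse-transcribed from oligo-dT primers. Arrays were grouped by their labels alone, and no group has a replicate. The number of arrays limits the precision of every value below, and no p-value is given.

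The values deposited by the authors are intensities of 54675 probe sets on a linear scale, rounded to 2 decimals and running from 0.05 to 265.58. RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of a set, is named per the submitters' processing notes, without a version or settings. RMA usually gives log2 values. The range of these values is that of a linear scale, and log2 was taken here before any difference, as had been laid down for that case. The divisor of the scale is not stated, so levels are in arbitrary units. The sorted values of the 4 arrays nearly coincided in the upper part of the range, with a median gap of 0.03 on the log2 scale. Rounding makes ratios of the lowest values coarse, so the sizes and ranks of differences that rest on a dim value are uncertain. Equalised distributions also mean that a change shared by most genes would not be seen.

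Probe sets were named from the platform annotation supplied with the series. Of the 42898 probe sets it lists, 41097 have exactly 1 symbol and 1801 have several, and the remaining 11777 probe sets are unnamed here. Gene identifiers of 41043 probe sets matched the current symbol table, and no symbol had to be changed. A gene was represented by its probe set with the highest mean over the 4 arrays among those with exactly 1 symbol, which gave 19775 genes. A gene was kept if the highest of its 4 values reached the median of all values, 0.38, and 13134 genes were kept. Several probe sets measured 10523 of the genes, and these can part for a gene named in the text, which gives only some such cases.

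The following differences were computed per gene. The difference with TGF-beta was taken within the vector arrays and within the arrays labelled DLC1. The difference between the arrays labelled DLC1 and vector was taken without and with TGF-beta. The interaction was the difference with TGF-beta in the arrays labelled DLC1 minus that in the vector arrays. A gene counted as changed if it differed by at least 2-fold, a log2 difference of 1 or more. A change was called in both states, or in both backgrounds, if it passed 2-fold in the same direction in the 2 differences that share no array, and its count was set beside the number expected of independent lists. The 4 arrays were also paired by DLC1, by TGF-beta and crosswise, counting genes whose lower value in one pair lay at least 2-fold above the higher value of the other.

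The 21 gene lists, the rule for named genes, the filter and the size rule were chosen before the data were examined. The lists cover relatives of DLC1, TGF-beta induced and repressed targets, bone-acting secreted factors, bone metastasis genes of this family of sublines, SRF and MRTF targets, YAP and TAZ targets, epithelial and mesenchymal markers, matrix, integrin and protease genes, and cell cycle genes. They also cover interferon response, NF-kappaB and chemokine, cholesterol synthesis, endoplasmic reticulum and amino acid stress, hypoxia and glycolysis, and heat shock genes, luminal, leukocyte, and endothelial and stromal markers, and housekeeping genes. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. It was said to stand apart below the 2.5th or above the 97.5th percentile, which describes these arrays and is no test of the conditions. Named genes were DLC1, the 10 highest and 10 lowest genes changed in both states or both backgrounds by the smaller of the 2 differences, the 5 highest and 5 lowest of each single difference, the 10 highest and 10 lowest of the interaction, and up to 6 members of each list per comparison with the biggest differences. One further gene and 1 further list are not reported here.

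Differences were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and cyclic loess with limma 3.58.1 in R 4.3.3. The rule for DLC1 in both states was tested on simulated data made from the 13134 kept genes. It recovered 94% of 50 genes changed by 1.25 on the log2 scale, all of those changed by 1.5 or more, and 0 of 12934 unchanged genes. For the difference between DLC1 and vector arrays without TGF-beta, the list method picked out 40 of 40 simulated lists of 20 genes shifted by 0.3 and 2 of 40 unshifted ones. In 100 simulations with no effect, with the spread of the interaction as the error, the interaction gave a mean of 2.09 genes past 2-fold and at most 6. That spread was a median-based value taken over many genes at once, which gives extreme genes little weight. This therefore sets no bound on the number to expect among dim genes.

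The alternatives were thresholds of 1.5-fold and 3-fold, no filter and a filter at the 75th percentile, the mean of a gene's probe sets, leaving out first the probe sets whose names mark shared sequence, quantile normalization again, cyclic loess, centring each array on the housekeeping list, and the mean over list members. Random lists matched on gene length, and genes chosen on their response in the arrays labelled DLC1, were added after the data had been seen.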

Results

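Gene expression was measured in SCP2 cells, a bone-colonising subline of the MDA-MB-231 breast cancer line, carrying either an empty vector or an overexpression construct for DLC1. DLC1 encodes a GTPase-activating protein and is known as a tumour suppressor. Both kinds of cells were profiled without and with TGF-beta, a cytokine stored in bone matrix. The study's title places the work in bone metastasis of breast cancer. Each of the 4 groups was measured on 1 array, with median intensities of 0.38 to 0.39, so no group has a replicate, and each difference with TGF-beta or between the arrays labelled DLC1 and vector compares 2 arrays. Of 19775 genes, 13134 were bright enough to be kept.

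The DLC1 transcript was examined first, since it bears on the labels. The brightest DLC1 probe set, 210762_s_at, read 1.77 in the vector array and 3.38 in the array labelled DLC1, a 1.91-fold difference. With TGF-beta it read 2.51 and 3.64, a 1.45-fold difference. Neither reached 2-fold, although the first did with arrays centred on the housekeeping list, at 1.05 on the log2 scale. Another bright probe set, 224822_at, went the other way, from 1.79 to 1.44 without TGF-beta and from 2.41 to 1.69 with it. The dim 220512_at read 0.26 and 0.18 without TGF-beta, and fell from 0.41 to 0.19 with it. The other 2 DLC1 probe sets stayed between 0.07 and 0.14 on every array. The transcript therefore does not settle which arrays hold the overexpressing cells, and these are called the arrays labelled DLC1 throughout.

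**Figure D1:**
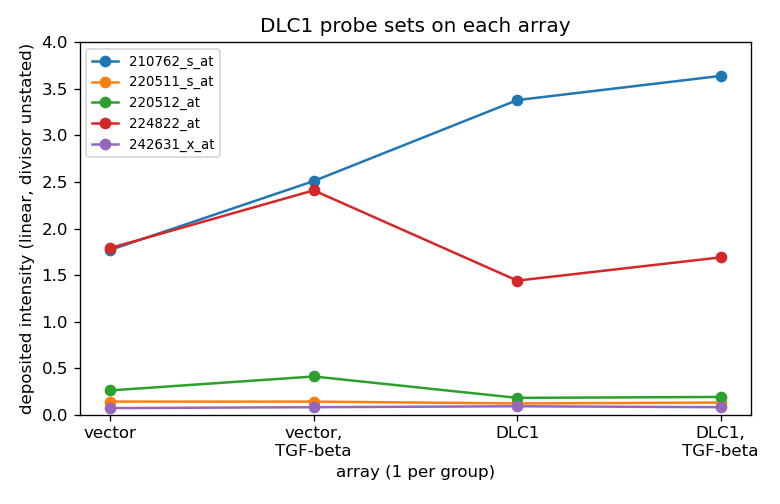
Intensity (linear, arbitrary units) of the 5 DLC1 probe sets on the 4 arrays, 1 per group; each coloured line joins the values of 1 probe set. The probe set 210762_s_at runs from 1.77 in the vector array to 3.64 in the array labelled DLC1 with TGF-beta, while 224822_at is highest, at 2.41, in the vector array with TGF-beta.

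Of the relatives of DLC1, STARD13, which encodes another GTPase-activating protein, fell by 1.11 on the log2 scale without TGF-beta and by 1.16 with it in the arrays labelled DLC1. STARD8 differed by -0.25 and 0.04. With TGF-beta the list of 3 had a median of 0.50 in the vector arrays, at the 99.4th percentile of random lists, and of 0.11 in the arrays labelled DLC1.

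The response of vector cells to TGF-beta asks what the cytokine does in these cells without added DLC1. PMEPA1, a feedback inhibitor of TGF-beta signalling, rose by 3.45 on the log2 scale, NEDD9, a scaffold protein of focal adhesions, by 3.44, and COL1A1, a chain of collagen I, by 3.37. ODAPH rose by 3.65 and the cadherin gene CDH19 by 3.14. In all, 157 genes rose and 90 fell. The genes that fell most were EREG, which encodes the growth factor epiregulin, at -2.50, SPRY1, an inhibitor of growth factor signalling, at -2.45 in its probe set 212558_at and -1.15 in 230212_at, CAVIN2 at -2.11, EVI2B at -2.07 and the thyroid hormone receptor gene THRB at -1.90. EREG read 0.79 and 0.14, the second at the 25th percentile of that array, so the size of its difference and its rank are uncertain. PTX3, which encodes a secreted pattern recognition protein, fell from 73.3 to 20.4 in intensity.

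In the arrays labelled DLC1, the question was whether the same response is seen with DLC1 added. CDH19 rose 12.2-fold and PMEPA1 12.2-fold, COL4A1, a chain of basement membrane collagen IV, rose 9.93-fold, and the metalloprotease gene ADAM19 7.87-fold. HTN1 rose by 2.93. Here 102 genes rose and 14 fell. SLC4A4, which encodes a bicarbonate transporter, fell by 2.01, KLRC3 by 1.58, HPGD, which encodes a prostaglandin-degrading enzyme, by 1.43, and INHBB, a subunit of activins and inhibins, by 1.32. The long noncoding RNA LINC00261 fell by 1.28. Without TGF-beta, CDH19, HTN1 and ADAM19 read 0.33, 0.28 and 0.15 in these arrays, under the filter. With TGF-beta, SLC4A4, KLRC3 and HPGD read 0.36, 0.19 and 0.29, also under the filter. The sizes of the differences that rest on these values are uncertain.

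The differences in the 2 backgrounds share no array. Of the changed genes, 80 rose in both and 8 fell in both, where independent lists would share 1.22 and 0.10, and 0 went opposite ways. The genes that rose most in both were PMEPA1, CDH19, COL4A1, ADAM19, COL1A1, the kinase anchor gene AKAP12, HTN1, the ephrin receptor gene EPHA4, ODAPH and the adhesion gene CNTN1, by between 2.42 for CNTN1 in the arrays labelled DLC1 and 3.65 for ODAPH in the vector arrays. The 8 that fell were PTX3, INHBB, LINC00261, SMIM31, the tetraspanin gene TSPAN8, the neuropeptide receptor gene VIPR1, the chemokine gene CCL20 and GDF15, which encodes a secreted stress-induced member of the TGF-beta family. Probe sets of COL1A1 parted: 202310_s_at gave 1.75 and 1.68, and 217430_x_at gave -0.11 and -0.33. For CDH19, 235639_at gave 1.84 and 1.30, and 1555403_a_at gave 1.89 and 0.79. For ADAM19, 221128_at gave 0.20 and 0.36. For CNTN1, 227202_at gave 3.25 and 1.39, and 211203_s_at gave 1.98 and 0.05. Across genes, which are not independent replicates, the 2 responses correlated with r = 0.69 and a rank correlation of 0.49.

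**Figure D2:**
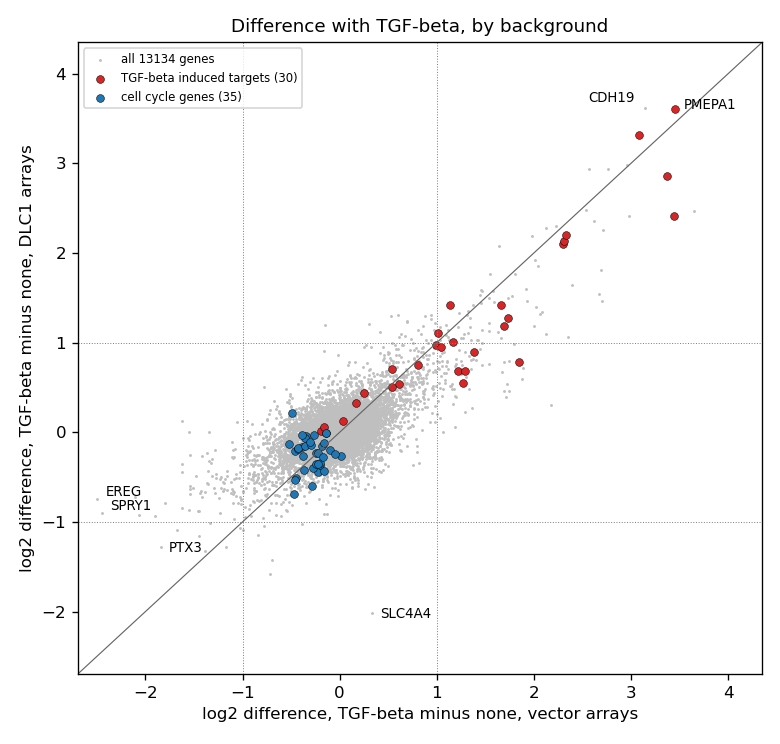
Log2 difference with TGF-beta in the vector arrays (x axis) and in the arrays labelled DLC1 (y axis) for 13134 genes, with TGF-beta induced targets in red and cell cycle genes in blue; dotted lines mark 2-fold and the solid line equal differences. PMEPA1 lies at 3.45 and 3.61, and most red points past 2-fold lie under the solid line.

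Among the fixed lists, TGF-beta induced targets moved most. Of 30 measured members, 19 rose in the vector arrays and 13 in the arrays labelled DLC1, and none fell. Besides PMEPA1, COL1A1, COL4A1 and NEDD9, COL4A2 rose by 2.33 and 2.20 and TGFBI, which encodes a matrix protein, by 2.31 and 2.13. The list's medians were 1.20 and 0.92, both above all 10000 random lists. None of the 4 measured TGF-beta repressed targets passed 2-fold: ID1 gave 0.21 and 0.32, ID2 0.17 and -0.09, ID4 0.02 and -0.18 and MYC -0.16 and -0.20. That list did not stand apart.

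Matrix, integrin and protease genes stood apart upward, with medians of 0.33 and 0.35 over 44 members. Of these, 10 rose and 1 fell in the vector arrays, and 9 rose in the arrays labelled DLC1. Examples beyond those above were COL6A3 at 2.61 and 2.36, and PLAU, the urokinase gene, at 1.55 and 1.77. The integrin gene ITGB8 fell by 1.31 in the vector arrays and gave -0.29 in the arrays labelled DLC1. SRF and MRTF targets, which include actin cytoskeleton genes, had medians of 0.24 and 0.22. The tropomyosin gene TPM1 rose by 1.33 and 1.11, and the caldesmon gene CALD1 rose by 1.08 in the vector arrays and gave 0.55 in the others. Mesenchymal markers had a median of 0.24 in each background. FN1, the fibronectin gene, and FAP, a fibroblast protease gene, rose by 1.38 and 1.18 in the vector arrays, and gave 0.89 and 0.06 in the arrays labelled DLC1. Epithelial markers did not stand apart. KRT7, a keratin gene, rose by 1.41 and 1.03, but its other probe set, 1558393_at, gave 0.20 and -0.09.

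Bone-acting secreted factors stood apart downward, with medians of -0.15 and -0.17 over 22 members, which went both ways. In the vector arrays 3 rose, namely BMP2 at 1.54, TNFRSF11B, which encodes the osteoclast inhibitor osteoprotegerin, at 1.06, and the cytokine gene IL11 at 1.04. The other kept sets of TNFRSF11B and IL11, 204932_at and 206926_s_at, gave 0.53 and 0.54. EREG, the macrophage growth factor gene CSF1 at -1.35, BMP4 at -1.08 and GDF15 at -1.03 fell. For CSF1, 210557_x_at and 211839_s_at gave -0.60 and -0.18. In the arrays labelled DLC1, GDF15 alone of this list passed 2-fold, at -1.07. Bone metastasis genes had a median of 0.18 in the vector arrays, at the 99.96th percentile, and 0.03 in the others, at the 88.1st. NF-kappaB and chemokine genes had medians of -0.38 and -0.41. CCL20 fell by 1.0 and 1.09, and IL1B gave -0.97 and -0.83. Cell cycle genes lay below 0 for 34 of 35 members in each background, with medians of -0.28 and -0.23 and none past 2-fold. Interferon response genes stood apart in the vector arrays, with a median of -0.14 at the 1.83rd percentile that was lost under 4 of the alternatives. Their median was 0 in the arrays labelled DLC1.

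YAP and TAZ targets had medians of -0.09 and 0.01 with TGF-beta, cholesterol synthesis genes 0.02 and -0.06, hypoxia and glycolysis genes 0.04 and -0.06 and heat shock genes -0.13 and -0.08, and none of these stood apart. Endoplasmic reticulum and amino acid stress genes had medians of 0.09, at the 99.25th percentile, and 0.02. Luminal markers had medians of 0.05 and -0.04, and endothelial and stromal markers 0.10 and 0.05. Leukocyte markers had medians of -0.24 and -0.25, the second at the 1.03rd percentile over 6 genes, and housekeeping genes 0.03 and -0.03. As a sign of RNA quality, the gap between the 5' and 3' control probe sets of beta-actin differed by 0.43 with TGF-beta in the vector arrays and by 0.08 in the others. The gap of GAPDH differed by 0.02 and -0.04.

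The comparison of the arrays labelled DLC1 with the vector arrays asks what added DLC1 changes in these cells. AGR2, which encodes a protein disulfide isomerase of the endoplasmic reticulum, rose 13.3-fold without TGF-beta and 13.9-fold with it, GDF15 9.30-fold and 9.05-fold, and LCN2, which encodes the iron-carrier protein lipocalin, 6.96-fold and 6.10-fold. SPP1, the gene of the bone matrix protein osteopontin, read 1.96 in the vector array and 0.17 in the array labelled DLC1, and 2.43 and 0.14 with TGF-beta. The lower values lie near the 25th percentile of each array, 0.14, so the size of the difference is uncertain. NRK, a kinase gene, was 7.94-fold and 7.95-fold lower, and MMP3, the stromelysin gene, 6.75-fold and 4.82-fold lower. Without TGF-beta 211 genes rose and 303 fell, and with TGF-beta 190 rose and 211 fell.

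In both states 112 genes rose and 144 fell. Independent lists would share 3.05 and 4.87, and 0 genes went opposite ways, where 7.77 would be expected. Besides AGR2, GDF15 and LCN2, the genes that rose most in both were ALDH8A1, the collagen IV gene COL4A3, the protocadherin gene DCHS1, the complement gene C3, INHBB, the transcription factor gene KLF9 and SDF2L1, which encodes an endoplasmic reticulum chaperone component. Their differences ran from 1.82 for SDF2L1 with TGF-beta to 2.87 for COL4A3 without it. Without and with TGF-beta, the vector arrays read 0.15 and 0.15 for ALDH8A1 and 0.1 and 0.23 for COL4A3. For DCHS1 they read 0.23 and 0.26, and for INHBB 0.26 with TGF-beta. These vector values lie under the filter, so the sizes and ranks of the differences that rest on them are uncertain. The genes that fell most, besides SPP1, NRK and MMP3, were the transcription factor gene POU3F2, the calcium-binding protein gene CALB1, the phosphatase gene PTPN22, DEPDC7, the fatty acid carrier gene FABP4, the mitotic motor gene KIF11 and the chemokine gene CCL2, at between -1.85 for CCL2 without TGF-beta and -2.54 for POU3F2 with it. The other kept set of POU3F2, 207084_at, gave -0.42 and -0.95. In the array labelled DLC1 without TGF-beta, NRK, POU3F2, PTPN22 and DEPDC7 read 0.31, 0.33, 0.3 and 0.24. These values lie under the filter too, so the sizes and ranks of those differences are also uncertain. In the single differences, NDP, which encodes a ligand of Wnt receptors, fell by 2.37 without TGF-beta, and ESM1 and the sulfotransferase gene SULT1B1 fell by 2.74 and 2.31 with it. The lower values of NDP and SULT1B1, 0.22 and 0.21, were likewise under the filter. Across genes, the differences in the 2 states correlated with r = 0.84 and a rank correlation of 0.80. Centring each array on the housekeeping list moved the median of all genes by 0.12 without and 0.11 with TGF-beta and turned the balance, to 175 genes higher and 109 lower in both states.

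**Figure D3:**
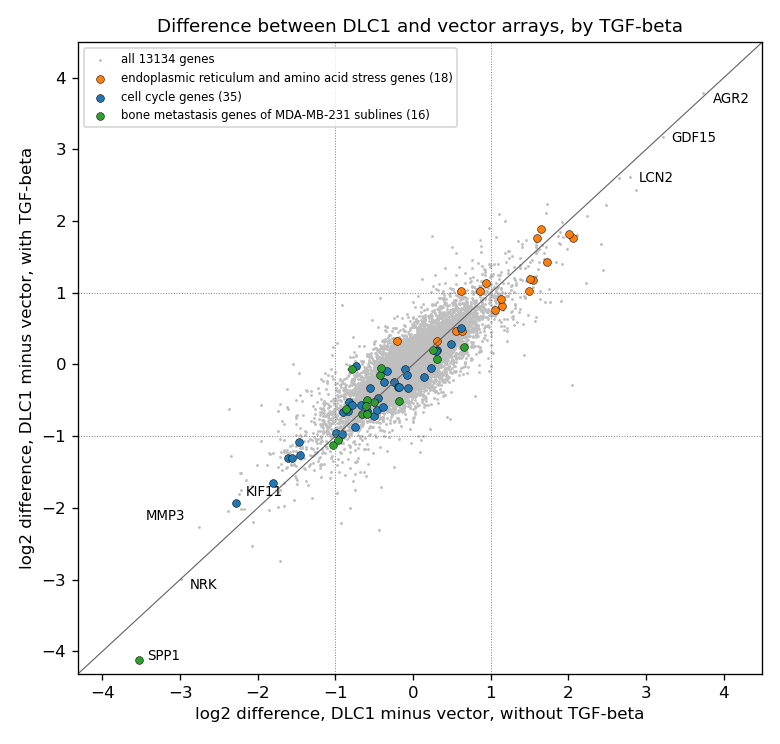
Log2 difference between the arrays labelled DLC1 and vector, without TGF-beta (x axis) and with it (y axis), for 13134 genes, with endoplasmic reticulum and amino acid stress genes in orange, cell cycle genes in blue and bone metastasis genes in green; dotted lines mark 2-fold and the solid line equal differences. Orange points reach 2.06 without TGF-beta, and SPP1 lies at -3.53 and -4.12, a size set by dim values in the arrays labelled DLC1.

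Endoplasmic reticulum and amino acid stress genes were higher as a group. Of 18 members, 11 rose without TGF-beta and 11 with it, 7 stayed within 2-fold in each state, and the medians of 1.14 and 1.03 lay above all 10000 random lists. TRIB3, a stress-induced pseudokinase gene, rose by 2.06 and 1.76, SDF2L1 by 2.01 and 1.82, VLDLR by 1.64 and 1.89, and DDIT4, an inhibitor of mTOR signalling, by 1.59 and 1.76. The chaperone genes DNAJB9 and HSPA5 rose by 1.73 and 1.54 without TGF-beta and by 1.43 and 1.17 with it. The transcription factor genes ATF4 and ATF3 gave 0.63 and 0.55 without TGF-beta, and 0.46 and 0.47 with it. The cystine transporter gene SLC7A11, the only member below 0, gave -0.21 and 0.32. On the same arrays, the 5', middle and 3' control probe sets of 18S ribosomal RNA were 0.84, 0.85 and 0.43 higher in the array labelled DLC1 without TGF-beta, and 0.35, 0.30 and 0.07 higher with it.

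Cell cycle genes were lower as a group, with medians of -0.50 and -0.53, both below all 10000 random lists. Of 35 members, 29 lay below 0 without TGF-beta and 31 with it, and 6 fell in each. KIF11 fell by 2.28 and 1.93, CENPE, a kinetochore motor gene, by 1.81 and 1.66, TOP2A, a topoisomerase gene, by 1.61 and 1.30, and the spindle checkpoint gene BUB1 by 1.56 and 1.31. KIF20A and BUB1B were the others. The proliferation marker MKI67 gave 0.61 and 0.51 in the probe set used and -0.95 and -0.77 in 212020_s_at. Long genes tended to be lower in the arrays labelled DLC1, with medians of -0.13 and -0.09 for the longest 10% of genes and a rank correlation with gene length of -0.14 and -0.10. Cell cycle genes also stood apart among random lists matched on length.

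Genes tied to bone metastasis were lower. In the list of bone metastasis genes of these sublines, 13 of 16 members lay below 0 in each state, with medians of -0.59 and -0.51, below all random lists. Without TGF-beta 2 of them fell and with it 3. SPP1 and IL11 fell in both states, IL11 by 1.03 and 1.12 in the probe set used, while its set 206926_s_at gave -0.85 and -0.77. The matrix protease gene ADAMTS1 fell by 1.06 with TGF-beta and gave -0.97 without it. The chemokine receptor gene CXCR4 gave -0.66 and -0.69, and CCN2, which encodes connective tissue growth factor, -0.50 and -0.52. Bone-acting secreted factors had medians of -0.43 and -0.47, and 4 and 5 of 22 members fell. CCL2 fell by 1.85 and 2.03, HBEGF by 1.16 without TGF-beta, and BMP2 and WNT5A by 1.52 and 1.40 with it. GDF15 rose in both states and CSF1 rose by 1.65 with TGF-beta in the probe set used. Its sets 210557_x_at and 211839_s_at gave 0.77 and 0.18 there. Some genes belong to both lists, which are therefore not independent of each other.

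Matrix, integrin and protease genes were lower, with medians of -0.30 and -0.42, and 6 and 5 of 44 members fell. ADAM19 fell by 1.77 and 1.75 and LAMB1, a laminin gene, by 1.33 and 1.27. THBS1, which encodes the TGF-beta activator thrombospondin, fell by 1.68 without TGF-beta and gave -0.78 with it in the probe set used. Without TGF-beta, 201109_s_at and 235086_at gave -1.40 and -1.64. The sets 239336_at, 215775_at, 201107_s_at and 201108_s_at stayed within 2-fold there, at -0.94, -0.69, -0.97 and -0.54. With TGF-beta, 201109_s_at, 235086_at, 239336_at and 215775_at gave -1.31, -1.48, -1.24 and -1.53, and 201107_s_at and 201108_s_at -0.88 and -0.78. TGF-beta induced targets stood apart downward, with a median of -0.22 in each state. In this list NEDD9 rose by 1.0 without TGF-beta, and SNAI2, a transcriptional repressor of epithelial genes, fell by 1.19 and 1.02. Without TGF-beta the list's position was lost, at the 19.4th percentile, when a gene was the mean of its probe sets. Mesenchymal markers did not stand apart, with medians of -0.15 and -0.19 and means of -0.34 and -0.36, although SNAI2 and TNC, the tenascin gene, fell in both states. SPARC fell by 1.07 without TGF-beta. Epithelial markers did not stand apart either, with medians of 0.16 and 0.11. JUP, which encodes plakoglobin, rose by 1.27 and 1.11, and CLDN1, a tight junction gene, rose by 1.34 with TGF-beta.

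SRF and MRTF targets had medians of -0.09 and -0.16, and had none of 24 members past 2-fold in the probe set used. They did not stand apart among lists matched on expression, but did with TGF-beta among lists matched on length, at the 2.14th percentile. Their member JUN gave -0.62 and -0.71 in the probe set used, but -1.25 and -1.41 in 201466_s_at. Its other kept sets, 201465_s_at and 213281_at, stayed within 2-fold. YAP and TAZ targets stood apart downward, with medians of -0.32 and -0.21, and IGFBP3 fell by 1.55 with TGF-beta. NF-kappaB and chemokine genes had medians of -0.38 and -0.35, and 14 of 18 members lay below 0 in each state. In the probe set used, CCL2 alone passed 2-fold. TNFAIP3 gave -0.81 and -0.89 in the probe set used and -1.07 and -1.17 in 202643_s_at. With a gene as the mean of its probe sets, the list's median without TGF-beta lay at the 5.35th percentile.

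Hypoxia and glycolysis genes had medians of 0.20 and 0.18, at the 99.7th and 99.4th percentiles. The iron- and hypoxia-responsive gene NDRG1 rose by 1.42 without TGF-beta, and ANKRD37 by 1.10 and 1.08. Both positions were lost when a gene was the mean of its probe sets, at the 97.15th and 96.5th percentiles. Cholesterol synthesis genes had medians of 0.22 and 0.16 with none past 2-fold, and the second position was lost under 4 alternatives and among lists matched on length, at the 96.21st percentile. Interferon response genes had medians of -0.02 and -0.09 and did not stand apart, although IFI27 rose by 1.38 and 1.20. Of 4 TGF-beta repressed targets, ID1, an inhibitor of differentiation factors, fell by 1.41 and 1.30. The list did not stand apart, except with TGF-beta among lists matched on length, at the 2.01st percentile. Heat shock genes had medians of -0.20 and -0.10, luminal markers -0.04 and 0.08, leukocyte markers -0.10 and -0.10, endothelial and stromal markers -0.05 and -0.07 and housekeeping genes -0.07 and -0.08, and none stood apart. Over all lists and comparisons, 44 of 105 medians stood apart, where 5.25 would be expected of random lists. Members of a fixed list may move together, some lists share genes and the comparisons share arrays. The excess over 5.25 therefore does not measure an effect of the conditions.

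**Figure D4:**
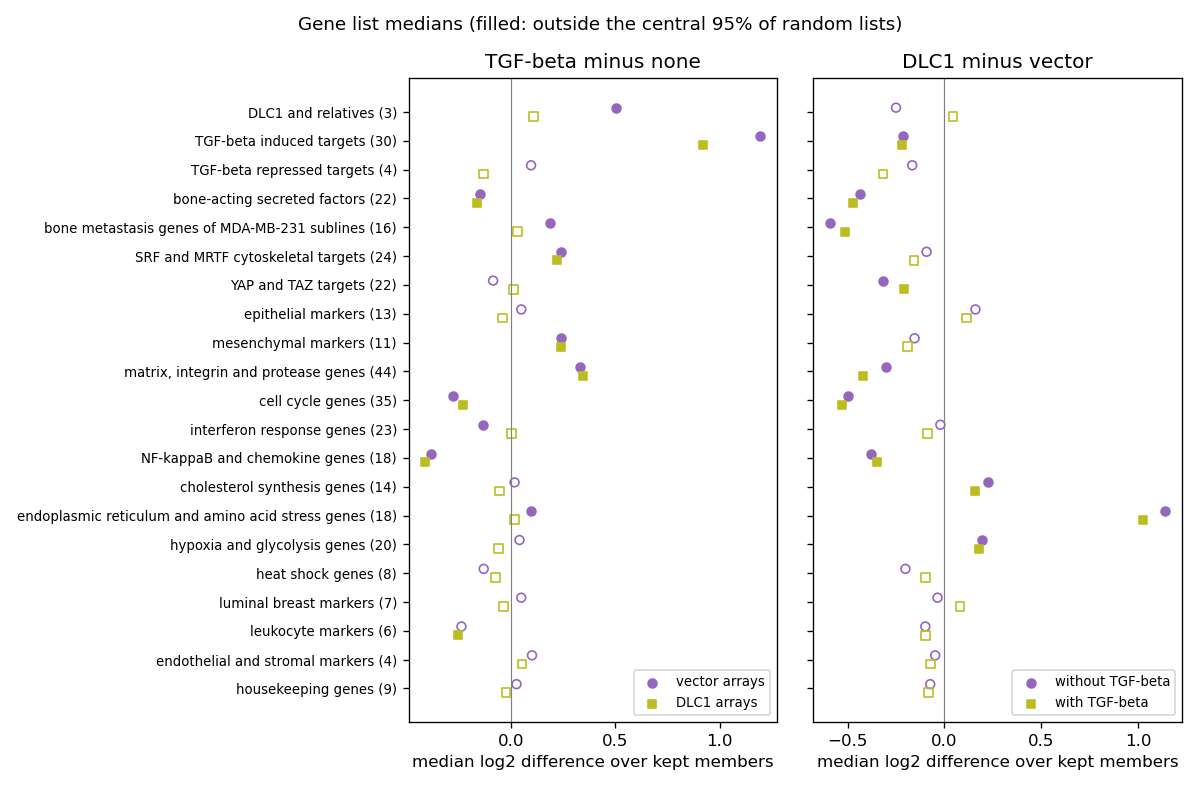
Median log2 difference of each of the 21 gene lists with TGF-beta (left) and between the arrays labelled DLC1 and vector (right); the number of measured members is in brackets, circles and squares are the 2 backgrounds or states, and filled symbols stand apart from random lists. Stress genes lie at 1.14 and 1.03 on the right, and TGF-beta induced targets at 1.20 and 0.92 on the left.

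The last comparison asked whether the response to TGF-beta differs between backgrounds. The interaction passed 2-fold for 48 genes, 25 higher and 23 lower, and for 21 with the filter at the 75th percentile. Several of the genes below have values near the dim end. Genes with the highest interaction had mostly fallen with TGF-beta in the vector arrays alone: EREG gave -2.50 there and -0.75 in the arrays labelled DLC1, SPRY1 -2.45 and -0.90, CAVIN2 -2.11 and -0.72, and GIMAP2, SHISA3, TXK and ANXA10 between -1.62 and -1.35 and between -0.35 and 0.00. The other probe set of SPRY1, 230212_at, gave -1.15 and -0.93, an interaction of 0.22, and that of CAVIN2, 218711_s_at, had an interaction of 0.69. NDP gave -1.62 and 0.13, SHROOM2, which encodes an actin-binding protein, -0.78 and 0.50, and GJB2, a connexin gene, -0.15 and 1.20. Without TGF-beta, GIMAP2, SHISA3, NDP and CAVIN2 read 0.38, 0.94, 1.14 and 4.15 in the vector array. In the array labelled DLC1 they already read 0.13, 0.34, 0.22 and 1.07 without it. For them a lost response cannot be told apart from a lower untreated level. SPRY1 was not lower there, at 4.26 against 3.61. Among the lowest, SLC4A4 gave 0.33 and -2.01. SULT1B1, GZMK, FAM83A, VASN, a TGF-beta-binding membrane protein gene, and LINC00842 rose in the vector arrays by 1.69 to 2.18 and gave 0.30 to 0.54 in the others. The transcription factor gene SOX4 rose by 1.88 and gave 0.59, SOX5 rose by 2.35 and 1.07, CDS1 by 2.70 and 1.46, with interactions of -0.49 and -0.14 in its other 2 kept probe sets, and ODAPH by 3.65 and 2.46. SOX4 went from 6.84 to 25.16 in the vector arrays and from 18.34 to 27.6 in the others, so it was higher there before TGF-beta.

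A gene picked on its response in one background tends to look smaller in the other. Of the 157 genes that rose in the vector arrays, 134 responded less in the arrays labelled DLC1, with medians of 1.35 and 1.0. Of the 102 that rose in the arrays labelled DLC1, 57 responded less there than in the vector arrays. Of the 90 that fell in the vector arrays, 87 responded less in the arrays labelled DLC1, but of the 14 that fell in the arrays labelled DLC1 only 5 did, with medians of -1.01 in the vector arrays and -1.15 in the others. With genes picked in either background, 77 rose in the vector arrays only and 22 in the arrays labelled DLC1 only, and 82 and 6 fell. Of the 30 TGF-beta induced targets, fixed beforehand, 19 responded less in the arrays labelled DLC1. Of their 19 members past 2-fold in either background, 15 did, among them NEDD9, BHLHE40 at 1.85 and 0.78 in the probe set used, and the integrin gene ITGA5 at 1.27 and 0.55. With TGF-beta, the sets used for NEDD9 and BHLHE40 read 5.09 and 21.03 in the vector array and 5.01 and 19.79 in the other. Without it they read 0.47 and 5.85, and 0.94 and 11.5, so their smaller difference goes with a higher untreated value. This did not hold for ITGA5, at 2.54 and 1.14 with TGF-beta, nor for 202150_s_at of NEDD9, at 1.64 and 0.96. The interaction median of this list was -0.08, at the 0.38th percentile, a position lost without the filter, at the 3.15th percentile, and with a gene as the mean of its probe sets, at the 2.5th. SRF and MRTF targets, NF-kappaB and chemokine genes, cholesterol synthesis genes and stress genes also stood apart downward in the interaction, with medians between -0.18 for stress genes and -0.07 for cholesterol synthesis genes. The position of cholesterol synthesis genes, at the 2.39th percentile, was lost under 4 alternatives and that of NF-kappaB and chemokine genes under 1. Epithelial markers lay just inside the bound, at the 2.56th percentile.

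Paired by DLC1, the 4 arrays gave 149 genes whose pairs were apart by 2-fold, 77 of them higher in the arrays labelled DLC1. Paired by TGF-beta they gave 39 genes, all higher with it. The crosswise pairing gave 0 genes.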

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

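All tests of explanations below were chosen after the results were seen. The first pattern is the group of endoplasmic reticulum and amino acid stress genes, TRIB3, SDF2L1 and HSPA5 among them, which was higher in the arrays labelled DLC1 by medians of 1.14 and 1.03. Random lists matched on expression reached at most 0.14 at the upper end of their central 95%, and lists matched on gene length 0.15, so neither scaling that depends on brightness nor the length trend accounts for it. A general stress of these cultures remains open: heat shock genes reached a median of no more than -0.10, while hypoxia and glycolysis genes reached 0.20. A difference between the cultures other than DLC1 cannot be told apart from DLC1 with 1 array per group. An effect of added DLC1 may therefore be offered only as a hypothesis, which was not tested.

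Fewer genes passed 2-fold with TGF-beta in the arrays labelled DLC1 than in the vector arrays. Picking genes on their response would, with equal error, leave genes past 2-fold in 1 background only about evenly divided. Of these, 77.8% of the induced ones (69.7% to 85.9% on resampling genes) and 93.2% of the repressed ones (87.5% to 97.7%) were past it in the vector arrays. The shares follow from the counts of genes past 2-fold, so they restate the pattern and cannot decide its cause. The ranges measure scatter over genes, which share the same arrays, and not the error of an array. A compressed scale would lower the SD of log2 values on the arrays labelled DLC1 in about the ratio of the response SDs, 0.78, and the ratio was 0.99. Equalised distributions hold that ratio near 1 in any case, so it cannot decide the question and a compressed scale stays open. Of the 14 genes that fell in the arrays labelled DLC1, only 5 responded less there. Larger error or a different RNA quality on a single vector array was not tested and stays open, as it would widen the response in vector cells. The 3 control probe sets of 18S ribosomal RNA differed with TGF-beta by 0.33 to 0.39 in the vector arrays and by -0.22 to 0.02 in the others, and the gap between the beta-actin controls by 0.43 and 0.08. With these explanations left open, a weaker response in cells with added DLC1 may be put forward only as a hypothesis.

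The DLC1 probe sets went opposite ways between the arrays labelled DLC1 and vector. Ordinary scatter between probe sets is an improbable account, since the 2 brightest sets of only 0.845% of 6388 genes parted as far in both states. TGF-beta labels exchanged between arrays would turn the TGF-beta induced targets downward, and the smaller of their medians was 0.92. An exchange of vector and DLC1 labels cannot be told apart from the labels as given, because the brightest set was higher by 0.54 or more in both states while the other 2 sets bright enough to be kept were lower. An expression construct without the part of the transcript that 224822_at and 220512_at read may account for the pattern together with a lower level of the cell's own transcript, but where the probe sets lie was not analysed here.

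Several of the named genes had differences of opposite sign in the 2 backgrounds or states, with an interaction past 2-fold. These differences were not tested, as no group has a replicate. The difference between the arrays labelled DLC1 and vector changed sign with TGF-beta for EREG (interaction 1.75), EVI2B (1.15), TXK (1.29), ANXA10 (1.27), CDS1 (-1.23), VASN (-1.23), FAP (-1.13), SLC4A4 (-2.34), GJB2 (1.35), GZMK (-1.32), BHLHE40 (-1.06) and NEDD9 (-1.02). The TGF-beta response changed sign between backgrounds for SLC4A4 and GJB2 as well, and for NDP (interaction 1.75) and SHROOM2 (1.29). For each, at least 1 of the 2 signs rests on a difference under 2-fold. For some it rests on rounded values at the dim end, as 0.22 and 0.24 for FAP and for NDP, 0.14 and 0.25 for EREG and 0.34 and 0.42 for TXK, so these signs are not settled. The other 2 kept probe sets of CDS1, 226185_at and 226187_at, gave interactions of -0.49 and -0.14, without a change of sign, and the other set of BHLHE40, 201169_s_at, gave -0.20.

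Signals also lay outside the named genes. Of 4798 bright probe sets without exactly 1 symbol, 82 differed by 2-fold between the arrays labelled DLC1 and vector in both states, 59 of them higher, and 17 differed with TGF-beta in both backgrounds, 14 of them higher. The 5' control probe set of 18S ribosomal RNA was 0.84 higher on the log2 scale in the array labelled DLC1 without TGF-beta than in the vector array.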

How the results depend on the processing

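Every alternative was laid down beforehand except random lists matched on gene length and genes chosen on their response in the arrays labelled DLC1, which were added after the data had been seen. No paired analysis was possible because each group holds 1 array and no replicate numbers join the groups. The 2 differences of each factor, which share no array, were set side by side instead. With 1 array per group leaving out a replicate was not possible. Signal over background limits the dim genes, whose rounded values move by large steps.

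The size threshold moved the counts that follow, by its construction. At 1.5-fold, 791 genes passed with TGF-beta in vector cells (410 higher, 381 lower), 438 in the arrays labelled DLC1 (302 and 136) and 312 in both backgrounds (221 and 91). Between the arrays labelled DLC1 and vector, 1925 passed without TGF-beta, 1646 with it and 1158 in both states. The interaction passed for 404 and the pairing by DLC1 gave 734. At 3-fold the counts were 67 (55 and 12), 30, 26, 106, 79, 50 (27 and 23), 4 and 27 in the same order. The filter at the 75th percentile, with fewer genes, left 258 genes between the arrays labelled DLC1 and vector with TGF-beta and 21 for the interaction, 7 higher and 14 lower against 25 and 23. It also left 58 lower genes with TGF-beta in vector cells against 90, 9 in the arrays labelled DLC1 against 14, and 117 higher between these arrays with TGF-beta against 190. With the mean of a gene's probe sets, 320 genes passed between these arrays without TGF-beta, 168 of them lower against 303, and 91 were lower in both states against 144. There 54 genes were lower with TGF-beta in vector cells and 8 in the arrays labelled DLC1, and 30 passed for the interaction, 15 each way. The cause was not tested. Under all other alternatives the totals over both directions stayed within 1.5 times their main values.

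Centring on housekeeping genes turned the split between the arrays labelled DLC1 and vector to 285 higher and 220 lower without TGF-beta against 211 and 303, to 265 and 159 with it against 190 and 211, and to 175 and 109 in both states against 112 and 144. It left 5 genes lower with TGF-beta in both backgrounds against 8. The turn follows from the shift of the median of all genes. The difference of the brightest DLC1 probe set without TGF-beta ran from 0.92 to 1.05 under the scalings. Of the 44 list positions that stood apart, 35 did so under every alternative of filter, gene value and scaling. The mean over members moved 30 of 105 list values by over 0.1 and housekeeping centring 40. With that mean, TGF-beta induced targets went from -0.22 to -0.10 between the arrays labelled DLC1 and vector without TGF-beta and from -0.08 to -0.17 in the interaction, and stress genes from -0.18 to -0.07 in the interaction. The value of lists that had not stood apart turned for interferon response genes with TGF-beta (-0.09 to 0.10), luminal markers without it (-0.04 to 0.23) and relatives of DLC1 with it (0.04 to -0.19), all between the arrays labelled DLC1 and vector, and others turned too. KRT7 with TGF-beta in the arrays labelled DLC1 went to -0.092 when probe sets of shared sequence were left out first, and the median of interferon response genes with TGF-beta in vector cells to 0.085 with the filter at the 75th percentile. The cause of neither was tested. The remaining values of named gene differences, summed over 7 alternatives, moved by less than 1.5 times in 1746 cases and by more in 65, of which 62 came with the mean of probe sets.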

Other observations

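Of the 80 genes that rose with TGF-beta in both backgrounds, 16 were lower in the arrays labelled DLC1 in both states. These were chosen after their values were seen. The differences share arrays, so no expected number is given. They were the ephrin receptor gene EPHA4, the semaphorin receptor gene NRP2, the myosin gene MYO10, the formin gene DAAM1, PRICKLE2, DCLK1, CDH19, CNTN1, ADAM19, AKAP12, ESM1, HECW2, MARCHF4, POU3F2, PRDM1 and UCN2. For several of them, CDH19 included, further kept probe sets did not pass 2-fold in all of these differences. The other kept set of ADAM19, 221128_at, passed it in none. In the opposite direction, GDF15, INHBB and SMIM31 fell with TGF-beta in both backgrounds and were higher in the arrays labelled DLC1 in both states, 3 of the 8 genes that fell. The collagen IV gene COL4A4 and MEGF6 were higher in both comparisons.

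Cell cycle genes were lower with TGF-beta and lower in the arrays labelled DLC1, and the members past 2-fold in the second comparison were KIF11, CENPE, TOP2A, BUB1, BUB1B and KIF20A. The probe sets of MKI67 parted: 212020_s_at and 212023_s_at gave -0.95 and -0.90 without TGF-beta, while 212021_s_at and 212022_s_at gave 0.61 and 0.28. No explanation was tested for this.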
